A study of Mus musculus with 12 samples.

How the data were processed

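RNA was measured in colon tumours of mice that carried transplanted bone marrow. Per the labels' protocols, wild-type (WT) or St2-/- recipients were lethally irradiated, received WT or St2-/- bone marrow and were later injected with azoxymethane (AOM), a chemical that induces colon tumours. St2KO stands below for St2-/-, and each group is written as marrow_to_host. Per the labels' protocols, total RNA of snap-frozen tumours was made into TruSeq RNA libraries and sequenced as single-end reads on an Illumina HiSeq instrument. The mice were of the Balb/c background, per the labels. All 12 libraries carried the same flow cell and lane in their labels.

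Per the submitters' processing notes, reads were aligned with TopHat and Bowtie2 to GRCm38 (mm10). Their versions, the counting tool, the annotation counted on and the strand setting were not given in the sources used here. The deposited values were raw read counts per gene, in 1 table of 24062 genes and 5 summary entries that name no gene, and no column lacked a sample (0). The summary entries had the form that htseq-count writes. They held 49.8% to 59.6% of each library's total, and alignments that were not unique made up 36.7% to 48.9%. They were left out of library sizes and tests. Because the strand setting is unknown, genes that overlap another gene on the opposite strand are less certain. Genes whose reads are shared with close relatives are also less certain, since reads with more than 1 best position were not counted for any gene. Of the genes, 99.4% matched a RefSeq symbol or synonym, 4368 had no count in any library, and none was on the mitochondrial genome. Coordinates came from GENCODE M21 on GRCm38.

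Gene counts per library lay between 10293818 and 12962496, and 16950 to 17697 genes had counts. Intervals and floors derived from counts cover counting error only. The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given and its minimum count of 10, which left 15060 genes and removed 9002. TMM factors lay between 0.899 and 1.12. A quasi-likelihood model with robust estimation had 1 coefficient for each of the 4 groups, and all comparisons were contrasts of these coefficients, so that all 12 libraries set the spread. Tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM are the usual depth-scaled counts of edgeR after TMM, and log2 fold changes are those of the edgeR model. Errors of log2 fold changes are standard errors (SE), and errors of CPM are standard deviations (SD) over the 3 libraries of a group.

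The comparisons, tests, alternatives and 37 gene lists were written before the data were examined. The lists covered responses, tissue components and cell types, and their 805 entries included 771 found in the table. Of the lists, 35 had at least 4 tested members and were tested. The mitochondrial genome list had no measured member, and the list for X inactivation was too short. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with the correlation between members estimated for each list, and adjusted over the 35 lists of a comparison. Members of lists were also counted by edgeR p-values adjusted over the list alone. Named genes followed a rule. In each comparison with calls these were up to 12 higher and 12 lower genes with the smallest p among called genes with a log2 fold change of at least 1 in size. Between single groups, the libraries were also required not to overlap, and where fewer than 5 genes passed in a direction all were named. Il1rl1, Il33 and up to 4 members with the smallest p of each list described were added. Predicted genes, clones, pseudogenes and sex-linked genes were not named by the first part of the rule. The comparisons within St2KO hosts and within St2KO marrow were given as counts, with lists only.

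Alternatives used DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, no filter, a filter of CPM 1 in at least 3 libraries, the replicate number as a block, weeks after AOM as a covariate, only the 2 groups compared, and each library left out in turn. Lists were also tested with the preset camera correlation of 0.01 and with fry. After the values had been seen, 3 alternatives were added. These were a smooth muscle score as a covariate, a leukocyte score as a covariate, and the removal of WT_to_St2KO replicates 2 and 3 together. Tables and figures were made with Python 3.11.15.

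The edgeR step was tested on simulated counts made from the means and sizes of the real libraries. For WT_to_St2KO against WT_to_WT, it recovered 21% of genes changed 2-fold and 64% of those changed 4-fold on 14890 genes, with 3 false among 88 calls. For the host effect averaged over marrows, it recovered 54% and 87% on 14877 genes, with 5 false among 146 calls. A planted list of 30 genes changed 2-fold was recovered by camera in both, with 0 false lists. The simulated genes varied independently of each other. The simulation therefore does not show what edgeR or camera recovers, or calls falsely, where genes are correlated, as members of a list can be.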

Results

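RNA was sequenced from 12 colon tumours, labelled as biological replicates, in a design that crossed the genotype of the transplanted bone marrow with the genotype of the irradiated host. Each of the 4 groups, WT_to_WT, St2KO_to_WT, WT_to_St2KO and St2KO_to_St2KO, had 3 libraries. Tumours were taken 13 or 14 weeks after the last AOM injection, from 11 males and 1 female, WT_to_St2KO replicate 3. The gene counts of a library summed to between 10293818 and 12962496. The labels of all WT hosts carried numbers of 5 digits and those of all St2KO hosts numbers of 3 digits, so cohort and host genotype cannot be told apart in any comparison of hosts. Entries that name no gene held 49.8% to 53.2% of the total in WT hosts and 52.3% to 59.6% in St2KO hosts, and alignments that were not unique 36.7% to 42.9% and 40.3% to 48.9%, with overlap between hosts in both. TMM factors were 0.899 to 0.986 in WT hosts and 0.968 to 1.12 in St2KO hosts. The first and second principal components of log2 CPM, taken over the most variable genes only, held 31.1% and 29.3% of their variance. The second separated the hosts, at 3.41 to 31.4 in WT hosts and -42 to -5.63 in St2KO hosts.

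Il1rl1, which encodes ST2, the receptor for interleukin-33, followed the genotype of the host. It lies on chromosome 1 from 40429570 to 40465415 on GRCm38. Its mean was 154 ± 112 CPM in WT_to_WT and 118 ± 78.4 CPM in St2KO_to_WT, against 14.8 ± 9.21 CPM in WT_to_St2KO and 10.7 ± 2.73 CPM in St2KO_to_St2KO (SD, n = 3 each). The 6 WT hosts lay between 36.5 and 275 CPM and the 6 St2KO hosts between 7.3 and 25 CPM, without overlap. Averaged over marrows, Il1rl1 fell by 3.42 on the log2 scale in St2KO hosts (SE 0.52, edgeR adjusted p = 0.00984). This call was lost when WT_to_St2KO replicates 2 and 3 were both left out, where the log2 fold change was -3.57. Which exons the allele lacks was not given in the sources used here, and reads remained in all St2KO_to_St2KO libraries. Between marrows, the log2 fold change of Il1rl1 was -0.38 in WT hosts (SE 0.66, adjusted p = 0.942) and was not called. It was above 0 there, at 0.34 without WT_to_WT replicate 3 and at 0.038 without St2KO_to_WT replicate 2. Il33, which encodes the ligand, was not called in any comparison. Its log2 fold change was -0.77 between hosts (SE 0.47, adjusted p = 0.371) and 1.05 between marrows (SE 0.47, adjusted p = 0.999).

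**Figure D1:**
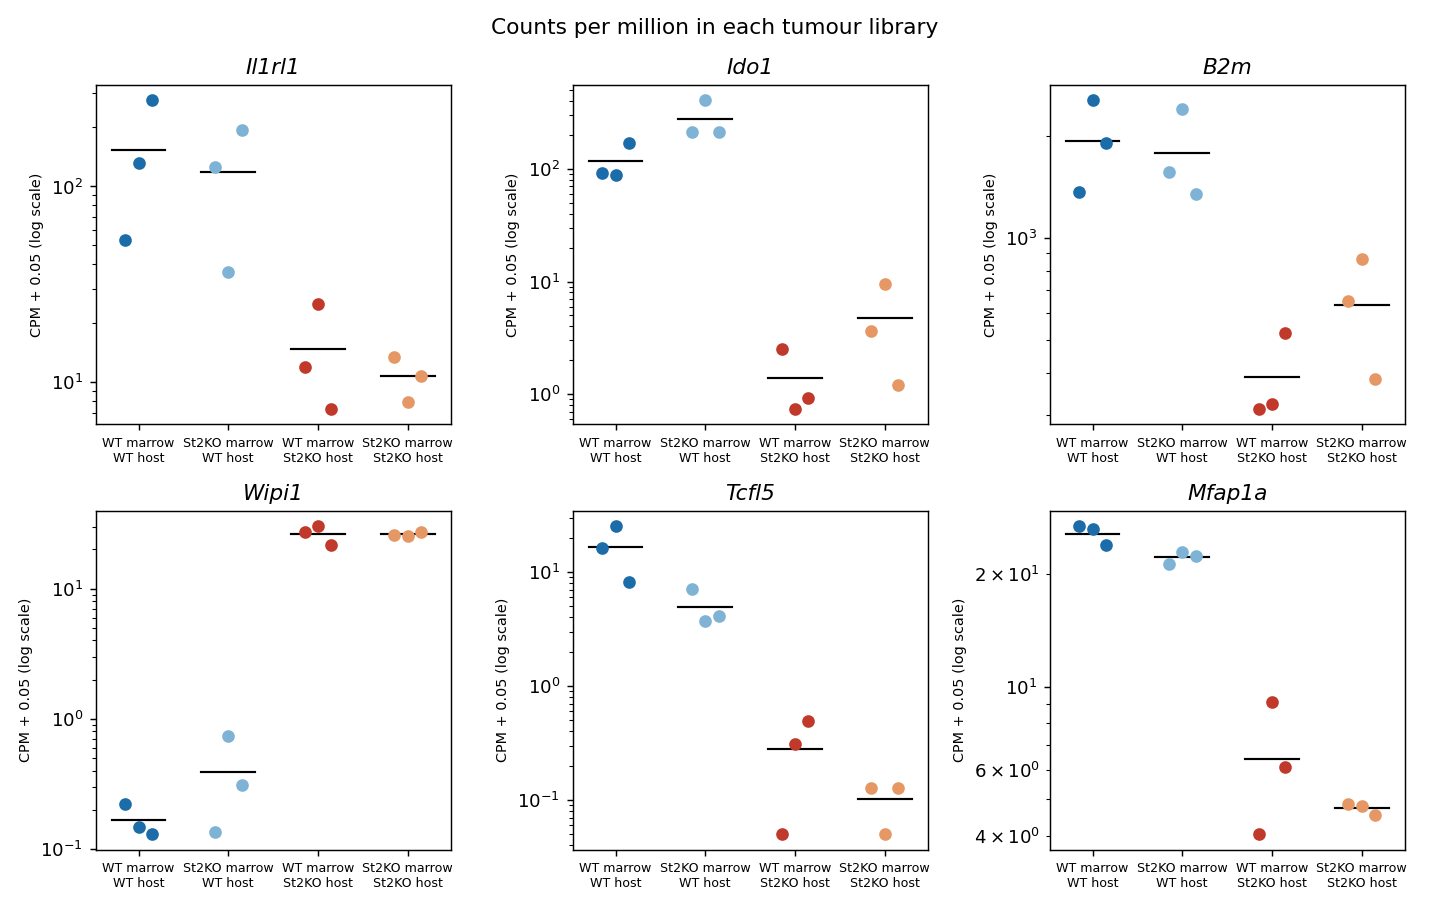
CPM plus 0.05 on a log scale for Il1rl1, Ido1, B2m, Wipi1, Tcfl5 and Mfap1a in each of the 12 libraries (points), by marrow and host genotype, with the mean of each group of 3 as a line. Il1rl1 lay between 36.5 and 275 CPM in WT hosts and between 7.3 and 25 CPM in St2KO hosts.

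The comparison of St2KO_to_St2KO with WT_to_WT asks what changes in the tumour when both host and marrow lack St2. Wipi1 rose, and Mfap1a, Tcfl5 and Arl2bp fell, and these were the only 4 of 15060 genes called by edgeR. Il1rl1 itself had a log2 fold change of -3.84 (SE 0.75, edgeR adjusted p = 0.148) and was not called, so large changes can be missed here. Wipi1, which encodes a phosphoinositide-binding protein of autophagy, rose by 7.69 on the log2 scale (SE 0.52, adjusted p = 0.000222), from 0.116 ± 0.049 to 26.1 ± 1.17 CPM (SD, n = 3). Mfap1a, a splicing factor gene, fell by 2.45 (SE 0.26, adjusted p = 0.0108), and Arl2bp, whose product binds the small GTPase ARL2, fell by 1.76 (SE 0.2, adjusted p = 0.0121). Tcfl5, a transcription factor gene, fell from 550 to 2 reads (adjusted p = 0.0121), a ratio of 308 with a 95% exact counting interval of 84.8 to 2550. Mfap1a shares sequence with Mfap1b, so its level is uncertain. On GRCm38, Wipi1 lies on chromosome 11 from 109573331 to 109611967, Mfap1a on chromosome 2 from 121491911 to 121506665, Tcfl5 on chromosome 2 from 180621956 to 180642708, and Arl2bp on chromosome 8 from 94666600 to 94674425.

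The lists of interferon and antigen presentation genes had negative medians in the same comparison, although no member was called over all genes. Adjusted over the list alone, 38 of 40 interferon-gamma response genes fell (median log2 fold change -2.11), as did 25 of 32 type I interferon response genes, 15 of 15 genes of MHC class I presentation and 9 of 22 Paneth-like and antimicrobial genes. Examples were Ido1, which encodes a tryptophan-degrading enzyme (-4.63, SE 0.67, adjusted p = 0.0647), and Psmb8, an immunoproteasome subunit gene (-1.90, SE 0.39, adjusted p = 0.148). The lowest adjusted p of a list was 0.505 with an estimated correlation, for the interferon-gamma response. At an unadjusted p under 0.05, edgeR gave 2067 genes against 753 expected by chance. DESeq2 called 473 genes and limma-voom 1722. The count was 8 with only the 2 groups compared, 8 with the smooth muscle score and 7 without WT_to_St2KO replicates 2 and 3. It was 7 without WT_to_St2KO replicate 1, 11 without replicate 2 of that group, and 1 without WT_to_WT replicate 2 or any 1 of the St2KO_to_St2KO libraries, where Wipi1 alone remained.

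WT_to_St2KO against WT_to_WT asks what loss of St2 in the host alone changes. Of 24 genes called, 6 rose and 18 fell. Ido1 fell by 6.43 on the log2 scale (SE 0.76, adjusted p = 0.0238), from 117 ± 46 to 1.34 ± 0.967 CPM (SD, n = 3). Fcgr4, an activating Fc receptor gene, fell by 2.53 (SE 0.32), Il18bp, which encodes the inhibitor of interleukin-18, by 2.26 (SE 0.31), and the atypical chemokine receptor gene Ccrl2 by 2.29 (SE 0.32), each with adjusted p = 0.0238. Slfn2 and Slfn5, of the Schlafen family, fell by 1.60 (SE 0.22, adjusted p = 0.0238) and 1.57 (SE 0.23, adjusted p = 0.0413). The MHC class I genes and partners among the calls were H2-Q2 (-2.20, SE 0.31, adjusted p = 0.0252), Psmb8 (-2.64, SE 0.4, adjusted p = 0.0413) and B2m, the light chain of class I molecules, whose adjusted p was 0.0458. Reads of H2-Q genes are shared among relatives, so H2-Q2 is uncertain. The interferon-inducible GTPase gene Ifi47 fell by 2.71 (SE 0.42, adjusted p = 0.0413).

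The 4 genes of the full comparison moved the same way when only the host lacked St2, but both comparisons use the same WT_to_WT libraries. Wipi1 rose by 7.70 (SE 0.52, adjusted p = 0.000222), and Mfap1a, Tcfl5 and Arl2bp fell by 2.01, 6.09 and 1.35 (adjusted p = 0.0238, 0.0238 and 0.0398). Gsdmc2, a gasdermin gene of the gut epithelium, rose by 3.32 (SE 0.41, adjusted p = 0.0238), from 71.5 ± 34.6 to 717 ± 159 CPM. It shares sequence with its neighbours Gsdmc3 and Gsdmc4 and is uncertain. Nrbp2, a pseudokinase gene, rose by 2.16 (SE 0.33, adjusted p = 0.0413) and Sfi1, a centrosome gene, by 1.64 (SE 0.26, adjusted p = 0.0458). Olfr76, an olfactory receptor gene, had 0 reads in WT_to_WT and 1.71 ± 0.734 CPM in WT_to_St2KO, which is at least 19.6-fold against a floor of 3 counts. Among all 24 calls, only Wipi1 was called under every setting, the count being 1 with only the 2 groups compared.

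By lists, 2 of 40 interferon-gamma response genes fell in this comparison and 39 fell adjusted over the list alone (median -2.64, adjusted p = 0.321 with an estimated correlation). MHC class I presentation gave 2 of 15 and 15 of 15, and the type I interferon response 1 of 32 and 25 of 32. Adjusted over the list alone, 16 of 26 macrophage and monocyte genes and 7 of 18 neutrophil genes fell, while 13 of 20 smooth muscle genes, 9 of 18 genes of enteric neurons and glia and 7 of 19 mast cell genes rose. None of these members was called over all genes. Muscle and neuron scores were highest in WT_to_St2KO replicates 2 and 3 within their group, and the smooth muscle score was 6.29 in replicate 2 against 3.50 in replicate 1. With that score as a covariate 3 genes were called, and 3 were called without both libraries. Weeks after AOM as a covariate left 5 genes.

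Single libraries set the number of calls between WT_to_St2KO and WT_to_WT, from Ido1 and Gsdmc2 to the interferon genes. The count was 58, 1 and 1 without WT_to_WT replicates 1, 2 and 3, and 142, 3 and 4 without WT_to_St2KO replicates 1, 2 and 3. It was 12, 49 and 13 without St2KO_to_WT replicates 1, 2 and 3, and 1 and 42 without St2KO_to_St2KO replicates 1 and 2. At an unadjusted p under 0.05 edgeR gave 2514 genes. DESeq2 called 746 and limma-voom 314.

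St2KO_to_WT against WT_to_WT asks what loss of St2 in the marrow alone changes. No gene was called by edgeR (lowest adjusted p = 0.798), 910 had an unadjusted p under 0.05 against 753 expected by chance, and DESeq2 and limma-voom also called 0. Ido1, Cd274, which encodes PD-L1, and the tryptophan-tRNA ligase gene Wars had log2 fold changes of 1.24 (SE 0.57), 0.76 (SE 0.33) and 0.47 (SE 0.2), all with an adjusted p of 0.798. Adjusted over the list alone, 10 of 20 smooth muscle genes, 8 of 18 genes of enteric neurons and glia and 1 of 18 B cell genes rose, and 1 of 20 endothelial genes, Vwf, fell (-1.38, SE 0.3). All had an adjusted p of 0.952 with an estimated correlation. The smooth muscle score was 5.82 and 5.26 in St2KO_to_WT replicates 1 and 2 and 4.01 in replicate 3.

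In St2KO hosts, the genotype of the marrow gave 0 calls by edgeR, with 610 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.256, for Gsdmc2. DESeq2 called 17 genes and limma-voom 4, and edgeR called 1 without WT_to_St2KO replicates 2 and 3 and 1 without WT_to_WT replicate 2. Of the lists, 12 of 20 smooth muscle genes, 4 of 19 mast cell genes, and 1 gene each of the goblet and Paneth-like lists fell adjusted over the list alone, and 1 B cell gene rose. The adjusted p of the mast cell and smooth muscle lists was 0.479 with an estimated correlation. Interferon-gamma response genes included Cxcl9, a T cell chemoattractant, at 2.93 (SE 1.0, adjusted p = 0.995) and Ido1 at 1.80 (SE 0.73, adjusted p = 0.995).

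Averaged over hosts, 6 libraries with St2KO marrow were compared with 6 with WT marrow, which asks for an effect of marrow St2 in either host. No gene was called by edgeR (lowest adjusted p = 0.999), 415 genes had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Ido1 had a log2 fold change of 1.52 (SE 0.46) and Cd274 of 0.70 (SE 0.24), both with an adjusted p of 0.999. No member of any list passed adjusted over the list alone, and the lowest adjusted p of a list was 0.928 with an estimated correlation, for the interferon-gamma response.

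St2KO_to_St2KO against St2KO_to_WT asks for the effect of the host where the marrow lacks St2. Of 9 genes called, 1 rose and 8 fell, and among the fallen were Ido1, by 5.87 (SE 0.71, adjusted p = 0.0177), and Wars, by 1.68 (SE 0.21, adjusted p = 0.0177). These were the 2 of 40 interferon-gamma response genes called over all genes, and 40 of 40 fell adjusted over the list alone (median -2.42, adjusted p = 0.447 with an estimated correlation). MHC class I presentation had 0 called and 15 of 15 adjusted over the list alone, and the type I interferon response 0 and 22 of 32. Stat2 and Trim30a of the latter had log2 fold changes of -1.15 (SE 0.19, adjusted p = 0.0676) and -1.45 (SE 0.26, adjusted p = 0.1). At an unadjusted p under 0.05 there were 1809 genes, and DESeq2 called 262 and limma-voom 2004.

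The count of 9 genes, Ido1 and Wars among them, also moved with the setting. It was 2 with only the 2 groups compared, 4 with weeks after AOM and 15 with the smooth muscle score. It was 1 without WT_to_WT replicate 3, St2KO_to_WT replicate 2, or St2KO_to_St2KO replicate 1 or 3. It was 2 without St2KO_to_St2KO replicate 2, 5 without WT_to_St2KO replicate 3 and 17 without St2KO_to_WT replicate 3.

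The 2 comparisons of hosts, one within each marrow, share no library. Of the 24 genes called with WT marrow, 21 had the same direction with St2KO marrow and 17 of these an unadjusted p under 0.05. All 9 genes called with St2KO marrow had the same direction with WT marrow, each with an unadjusted p under 0.05. The calls shared 5 genes, against 0.014 expected for independent lists. All 82 different genes of the interferon-gamma, type I interferon and MHC class I lists had negative fold changes in both. Across all 15060 genes the Pearson correlation of log2 fold changes was 0.156, and genes are not independent replicates.

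**Figure D2:**
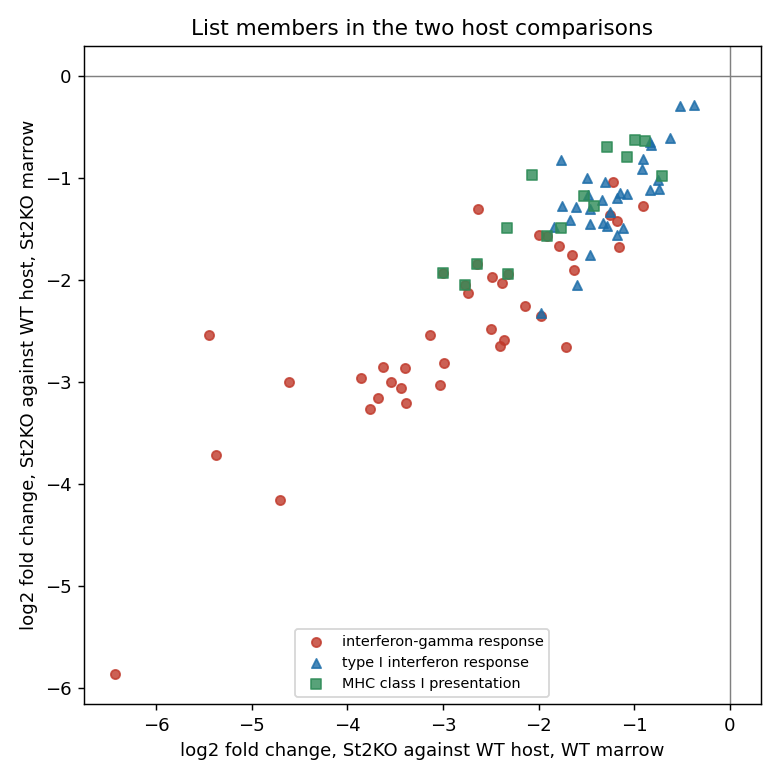
Log2 fold change of St2KO against WT hosts with WT marrow (x axis) and with St2KO marrow (y axis) for each tested member of the interferon-gamma response, type I interferon response and MHC class I lists (points, 1 per gene and list). All 82 different genes lie below 0 on both axes, and the lowest point is Ido1 at -6.43 and -5.87.

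Averaged over marrows, the 6 St2KO hosts were compared with the 6 WT hosts, which asks for the effect of host St2 with either marrow. Of 206 genes called by edgeR, 44 rose and 162 fell, and genes of the interferon response and of antigen presentation made up 58 of those that fell. Ido1 fell by 6.15 on the log2 scale (SE 0.52, adjusted p = 0.000865). Wars fell by 1.42 (SE 0.14, adjusted p = 0.00245), Cd274 by 2.20 (SE 0.25, adjusted p = 0.00325), and the transcription factor genes Stat2 and Irf1 by 1.15 (SE 0.13, adjusted p = 0.00325) and 1.76 (SE 0.21, adjusted p = 0.00331). Il18bp fell by 1.94 (SE 0.22), Slfn2 by 1.40 (SE 0.15), Slfn5 by 1.51 (SE 0.17), the surface protein gene Ly6c1 by 2.19 (SE 0.25) and Htatip2, an oxidoreductase gene, by 1.18 (SE 0.14), each with adjusted p = 0.00325. On GRCm38, Ido1 lies on chromosome 8 from 24584136 to 24597009, Wars on chromosome 12 from 108860030 to 108894174, and B2m on chromosome 2 from 122147686 to 122153083.

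Of the lists tested, the interferon-gamma response had the most members called between hosts. Of its 40 members 36 fell, and 40 adjusted over the list alone (median -2.45). Nlrc5, Tap1, Tap2, Psmb8 and Psmb9 belong to this list and also to MHC class I presentation, so the lists are not independent. MHC class I presentation had 14 of 15 that fell (15 adjusted over the list alone), among them Psmb8 (-2.24, SE 0.28, adjusted p = 0.00454), B2m (-1.91, SE 0.26, adjusted p = 0.00698), the peptide transporter gene Tap2 (-1.74, SE 0.24, adjusted p = 0.00737) and H2-T23 (-1.35, SE 0.19, adjusted p = 0.00765). The type I interferon response had 11 of 32 that fell (29 adjusted over the list alone), including Trim30a (-1.45, SE 0.18, adjusted p = 0.00473), Herc6 (-1.39, SE 0.21, adjusted p = 0.00984) and the oligoadenylate synthetase-like gene Oasl2 (-1.54, SE 0.25, adjusted p = 0.0131). In MHC class II presentation 2 of 13 fell (9 adjusted over the list alone), the invariant chain gene Cd74 (-1.84, SE 0.37, adjusted p = 0.0399) and H2-DMa (-1.46, SE 0.31, adjusted p = 0.0493). Of 94 tested genes in these 4 lists, 1 was expected among the 162 by chance (Fisher's exact test, two-sided, p = 6.29e-94, genes not independent), and 0 were among the 44 that rose.

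Against all other genes, camera gave the interferon-gamma response an unadjusted p of 0.00999 and an adjusted p = 0.255 with an estimated correlation, which was 0.663 between members. The values were 0.255 for MHC class I, 0.296 for the type I interferon response and 0.547 for MHC class II. No list was called with an estimated correlation in any of the 8 comparisons, so none of the calls with the preset correlation held, 17 of them between hosts. By fry, which asks whether a list moves on balance in one direction and does not compare it with other genes, 4 of 35 lists were called between hosts, all downward. These were the interferon-gamma response and MHC class I (both adjusted p = 0.00193), the type I interferon response (0.0123) and cytotoxic T and NK cells (0.0182).

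Among immune cell lists, 2 of 17 genes of cytotoxic T and NK cells fell in St2KO hosts (9 adjusted over the list alone, adjusted p = 0.296 with an estimated correlation). Ifng, which encodes interferon-gamma, fell by 4.57 (SE 0.73, adjusted p = 0.0124), with 116 reads in the 6 WT hosts and 5 in the 6 St2KO hosts. Klrk1, which encodes the receptor NKG2D, fell by 1.98 (SE 0.38, adjusted p = 0.0345). In macrophages and monocytes 1 of 26 fell (1 adjusted over the list alone), the chemokine gene Ccl8 (-1.59, SE 0.33, adjusted p = 0.0426). In dendritic cells 1 of 16 fell (3 adjusted over the list alone), Clec9a, a receptor gene of cross-presenting cells (-1.36, SE 0.26, adjusted p = 0.033). Of 19 mast cell genes 1 rose and 1 fell, Tpsab1, a tryptase gene (3.60, SE 0.67, adjusted p = 0.0291), and Il1rl1, and adjusted over the list alone 8 rose and 1 fell. Reads of mast cell proteases are shared among relatives, so Tpsab1 is uncertain. Neutrophil genes had 0 of 18 called and 1 that fell adjusted over the list alone, and lists of helper and regulatory T cells (19 tested), eosinophils and type 2 lymphoid cells (11), B cells and follicles (18) and plasma cells (12) had 0 by both counts.

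Of the remaining lists between hosts, the Paneth-like and antimicrobial list had 1 of 22 that fell, Nos2, which encodes inducible nitric oxide synthase (-2.83, SE 0.58, adjusted p = 0.0416), and 7 that fell and 1 that rose adjusted over the list alone. Nos2 is also a member of the interferon-gamma list. The interleukin-33 and ST2 list had 2 of 11 that fell, Il1rl1 and the adaptor gene Myd88 (-0.53, SE 0.11, adjusted p = 0.0499), by both counts. Adjusted over the list alone, 8 of 24 hypoxia and glycolysis genes and 3 of 32 inflammatory cytokine genes fell, the latter with Tnf at -1.01 (SE 0.22, adjusted p = 0.0502), and of 23 goblet cell genes 1 rose and 1 fell. None of the 20 tested neighbours of Il1rl1 was called. No member was called by either count among absorptive colonocytes, tuft cells, enteroendocrine cells, stem cells and Wnt targets, the cell cycle, immediate early genes, metalloproteinases, fibroblasts and matrix, smooth muscle, endothelium, enteric neurons and glia, adipocytes, erythroid cells, squamous epithelium, distal Hox genes and Y-linked genes. Median and test differed in sign for fibroblasts (median -0.06, test upward), eosinophils (0.10, downward), adipocytes (0.04, downward) and enteroendocrine cells (0.08, downward), and the means of these lists were 0.07, 0.01, 0.06 and -0.02.

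The other genes named between hosts were outside these lists. Wipi1 rose by 6.95 (SE 0.35, adjusted p = 9.08e-06), with 21.5 to 30.2 CPM in St2KO hosts and 0.0796 to 0.686 CPM in WT hosts. Tcfl5 fell by 6.20 (SE 0.6, adjusted p = 0.00184), Mfap1a by 2.12 (SE 0.18, adjusted p = 0.000865) and Arl2bp by 1.51 (SE 0.14, adjusted p = 0.00177), and Mfap1b, the near copy of Mfap1a, by 1.52 (SE 0.23, adjusted p = 0.00987). Sfi1 rose by 1.53 (SE 0.19, adjusted p = 0.00399), Smco3 by 2.75 (SE 0.35, adjusted p = 0.00473), the mitochondrial chaperone gene Hspe1 by 1.26 (SE 0.19, adjusted p = 0.00926) and the forkhead gene Foxn3 by 1.43 (SE 0.21, adjusted p = 0.00937). Klhl30, Nrbp2, Ptprv and the homeobox gene Cux2 rose by 3.00, 1.27, 1.67 and 2.30 (SE 0.52, 0.23, 0.3 and 0.45), with adjusted p = 0.0204, 0.0246, 0.0246 and 0.0348. Olfr76 rose from 0.158 ± 0.213 to 1.48 ± 0.579 CPM (SD, n = 6, edgeR adjusted p = 0.00937). Of the 206 genes, 135 changed at least 2-fold, 122 of them lower.

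The number of genes called between hosts depended on the tool and on single libraries, while the interferon-gamma list stayed lower. DESeq2 called 1196 genes and limma-voom 1858, each with 40 of 40 interferon-gamma genes lower, and edgeR gave 3099 genes at an unadjusted p under 0.05. With the smooth muscle score 327 genes were called and with the leukocyte score 119. Without WT_to_St2KO replicates 2 and 3, 8 genes were called, and 1 of 40 interferon-gamma genes, with a median of -2.38. The count was 130, 121 and 95 without WT_to_WT replicates 1, 2 and 3, 132 and 86 without St2KO_to_WT replicates 1 and 2, and 80, 128 and 84 without St2KO_to_St2KO replicates 1, 2 and 3. It was 484 without WT_to_St2KO replicate 1. With any single library left out the interferon-gamma list kept at least 28 of 40 members called. Wipi1, Mfap1a, Tcfl5, Arl2bp, Wars, Slfn2 and Slfn5 were called under every setting. Klhl30, Nrbp2, Ptprv, Tpsab1, Cux2, Cd74, H2-DMa and Klrk1 each lost the call without any of at least 4 single libraries, and Oasl2 and Ifng without either of 2.

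The interaction asks whether the effect of the marrow differs between hosts. No gene was called by edgeR (lowest adjusted p = 0.119, for Gsdmc2), 1144 genes had an unadjusted p under 0.05, and DESeq2 called 93 genes and limma-voom 4. Without WT_to_St2KO replicates 2 and 3 edgeR called 1. Adjusted over the list alone, 16 of 20 smooth muscle genes (median -4.05) and 15 of 18 genes of enteric neurons and glia (median -4.89) had negative and 7 of 26 macrophage and monocyte genes positive differences, each list with an adjusted p of 0.639 with an estimated correlation. Members called over all genes were 0. The muscle and neuron transcripts were high in St2KO_to_WT replicates 1 and 2 and WT_to_St2KO replicates 2 and 3. Il1rl1 and Il33 were not called (adjusted p = 0.989 and 0.975).

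Sex-linked genes were read in each library. Xist, the RNA of the inactive X chromosome, was at 2013 CPM in the female library, WT_to_St2KO replicate 3, and between 14.6 and 87 CPM in the 11 male libraries. The 4 Y-linked genes measured summed to 0.186 CPM in the female library and to a mean of 221 CPM in the male libraries. Of these genes, Eif2s3y was at only 11.7 CPM in the male library St2KO_to_St2KO replicate 2, against 85.4 to 120 CPM in the other male libraries. Ddx3y, Kdm5d and Uty were at 69.8, 18.6 and 28.6 CPM there, within the range of the other male libraries.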

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

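Of 59 values of called genes, none reversed under any alternative, and the cause of the changes below was not tested. The smooth muscle and leukocyte scores and the removal of WT_to_St2KO replicates 2 and 3 were chosen after the values had been seen. For St2KO_to_St2KO against WT_to_WT (4 genes), DESeq2 called 473, limma-voom 1722, the 2 groups alone 8, the muscle score 8 and the removal of the 2 libraries 7. For WT_to_St2KO against WT_to_WT (24), the values were 746, 314, 1, 3 and 3, and 5 with weeks after AOM. For marrow in St2KO hosts (0), DESeq2 called 17, limma-voom 4 and the removal 1. For hosts with St2KO marrow (9), the values were 262 by DESeq2, 2004 by limma-voom, 2 with the 2 groups alone, 4 with weeks and 15 with the muscle score. For the average host effect (206), DESeq2 called 1196, limma-voom 1858, the muscle score 327, the removal 8 and the leukocyte score 119. The share of lower genes was 78.6%, and 57.3% by DESeq2 and 59.3% by limma-voom. For the interaction (0), DESeq2 called 93, limma-voom 4 and the removal 1. The replicate number as a replicate block gave 1, 13 and 1 genes in the comparisons with 4, 24 and 9, and changed the number called by no more than 1.5 times elsewhere. The numbers did not pair the libraries, since the deviations of 18 pairs with the same number correlated between -0.44 and 0.31 (mean -0.06), 5 of them over 0.1, and 1 library correlated best with its own number. With each library left out, the counts ranged from 1 to 11 (full loss), 1 to 142 (host, WT marrow), 0 to 1 (marrow, St2KO hosts), 1 to 17 (host, St2KO marrow) and 80 to 484 (average host), and stayed at 0 for the other comparisons. No list was called with an estimated correlation under any setting. The preset correlation called 11, 18, 8, 15, 13, 11, 17 and 13 lists in the order full loss, host with WT marrow, marrow in WT hosts, marrow in St2KO hosts, host with St2KO marrow, average marrow, average host and interaction, and fry called 2, 4, 0, 0, 2, 0, 4 and 0. Reversed values were all of Il1rl1 and Il33 where they were not called. With limma-voom these were Il33 in full loss (-0.19), Il1rl1 for marrow in St2KO hosts (0.18) and Il1rl1 (1.29) and Il33 (0.21) in the interaction. In the interaction, Il1rl1 was 0.42 with the muscle score and 0.22 with the removal, and Il33 was 0.017 with the replicate block and 0.33 with the muscle score. With each library left out, Il33 ranged from -0.13 to 1.02 in full loss, -1.09 to 0.059 for host with WT marrow, -1.27 to 0.19 for host with St2KO marrow and -0.93 to 0.87 in the interaction. Il1rl1 ranged from -0.93 to 0.34 for marrow in WT hosts, -0.79 to 0.15 for marrow in St2KO hosts and -0.81 to 0.53 in the interaction. Among called genes, 378 values under alternatives written before the data were examined were the same and 58 lost the call, 516 and 192 with each library left out, and 86 and 68 under the added alternatives.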

Other observations

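The tests of the leukocyte score, the smooth muscle score and the place of the interferon list among other genes, all tests of the 4 genes called in full loss, and both tests of Xist were chosen only after the result was seen, while the splits and the tests of DESeq2 size factors and cohort were written before.

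Genes of the gasdermin C family were highest where only the host lacked St2, a group of genes picked after the values had been seen. Gsdmc2, which was also named in that comparison, was at 71.5 ± 34.6 CPM in WT_to_WT, 199 ± 58.8 in St2KO_to_WT, 717 ± 159 in WT_to_St2KO and 90.7 ± 23.7 in St2KO_to_St2KO (SD, n = 3). Gsdmc3 was at 17.1, 60.9, 197 and 21.8 CPM and Gsdmc4 at 20.5, 46.1, 141 and 16.8 CPM in the same order. In the interaction Gsdmc2 had -4.46 (SE 0.56, edgeR adjusted p = 0.119), Gsdmc3 -5.01 (SE 0.88, adjusted p = 0.539) and Gsdmc4 -4.23 (SE 0.81, adjusted p = 0.539), so none was called. The 3 genes lie side by side and share sequence, so they are not independent.

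Proteases of mast cells were highest in the same group, WT_to_St2KO, and were also picked after the values had been seen. Tpsab1 was at 54.7 ± 40.8 CPM there and at 1.40, 0.981 and 3.82 CPM in WT_to_WT, St2KO_to_WT and St2KO_to_St2KO. Mcpt1 was at 528 ± 582 CPM against 62.1, 68.5 and 105 CPM, and Mcpt2 at 252 ± 259 CPM against 26.6, 34.5 and 53.3 CPM (SD, n = 3). The spread within WT_to_St2KO was as large as the mean for Mcpt1 and Mcpt2, and only Tpsab1 was called between hosts (adjusted p = 0.0291). The mast cell score of this group was 3.59, 4.99 and 2.62 in replicates 1, 2 and 3. It was 2 to 2.49 in WT_to_WT, 1.45 to 2.82 in St2KO_to_WT and 2.65 to 2.87 in St2KO_to_St2KO. Replicate 3 of WT_to_St2KO thus lay within the range of the other groups. Replicate 2 also had the highest smooth muscle score of all libraries, 6.29.

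The lower interferon response of tumours in St2KO hosts was seen with both marrows. DESeq2 size factors moved the fold change of the median gene by only 0.0034 on the log2 scale, with 202 genes called against 206, so the 36 of 40 members called with them are no test of normalization. Different amounts of muscle layer do not account for a fall with both marrows. The median of the smooth muscle list was 2.19 with WT marrow and -1.86 with St2KO marrow, where that of the interferon-gamma list was -2.64 and -2.42. The smooth muscle score as a covariate adds no test. Its mean was 4.26 in WT hosts and 4.32 in St2KO hosts, and it moved the median gene by only 0.0066. With it the genes called changed from 206 to 327, and 36 members stayed called with a list median of -2.45. A wrong scaling factor per library moves all genes alike, whereas 0.2% of 15020 other genes lay at or below the list median of -2.45. TMM sets the other genes near 0 (median -0.00024), so this share is no test of the scaling itself. It shows only that the list fell relative to other genes. A smaller share of leukocytes could lower such genes, but with the leukocyte score as a covariate, which moved the median gene by 0.056, 27 members stayed called and the list median was -2.34. That score overlapped between hosts, at 4.43 to 5.73 in WT hosts and 3.78 to 5.92 in St2KO hosts. The score of cytotoxic T and NK cells, whose list holds Ifng, did not overlap, at 1.23 to 2.34 and -0.536 to 1.05. It was not used as a covariate, so a smaller share of these cells stays open. A difference between 2 cohorts stays open, because 0 series of label numbers held both host genotypes, and a repeat with hosts of both genotypes in 1 cohort would tell it apart from St2.

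Wipi1, Mfap1a, Tcfl5 and Arl2bp differed between hosts also with an interferon score as a covariate. With it 4 of 4 kept the host effect (edgeR p adjusted over the 4 genes 6.18e-05, 0.00219, 0.00219 and 0.0111). The score did not overlap between hosts, at 5.75 to 7.6 in WT hosts and 3.45 to 5 in St2KO hosts. The SE rose with it, from 0.35 to 0.93 for Wipi1 and from 0.14 to 0.42 for Arl2bp. Host and interferon response can therefore hardly be separated, and a consequence of the lower interferon response stays open. Within hosts, the correlations with the score were 0.29, -0.29, -0.36 and -0.1. Between hosts, the score was lower in St2KO hosts, where Wipi1 was higher and Mfap1a, Tcfl5 and Arl2bp were lower. Each correlation within hosts was thus opposite in sign to the relation of gene and score between hosts. A segment of another strain around Il1rl1 does not reach them, with 0 of 4 within 20 Mb of it. Other differences between the colonies could show wherever St2KO cells are, and in WT hosts St2KO against WT marrow gave log2 fold changes of -1.74 for Tcfl5 (SE 0.6, p adjusted over the 4 genes 0.0589, 171 reads against 550), 1.49 for Wipi1 (SE 0.65, 0.0859, 12 against 4), -0.215 for Mfap1a (SE 0.24, 0.527, 769 against 884) and -0.101 for Arl2bp (SE 0.2, 0.618, 5299 against 5650). The 4 genes were chosen against the same WT_to_WT libraries, which favours moves in the direction of the St2KO hosts in this marrow comparison. Differences between the colonies stay open, because a difference in host cells alone would not show there. The host genotype also cannot be told apart from the colony. Sequence variants at these genes in the reads would test such differences.

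In tumours labelled male, Xist reads rose with leukocyte genes, and over these 11 libraries Xist correlated with the leukocyte score at r = 0.899 (permutation p = 0.00018, adjusted 0.00045 over 5 relations) and rho = 0.918 (permutation p = 0.00028, adjusted 0.0007), and at r = 0.82 without the 2 farthest libraries. Of the other relations, Ptprc, the pan-leukocyte gene, gave r = 0.953 (permutation p = 2e-05, adjusted 0.0001) and rho = 0.936 (p = 7e-05, adjusted 0.00035), the smooth muscle score 0.502 (p = 0.116, adjusted 0.193) and 0.6 (p = 0.0556, adjusted 0.0695), Y-linked genes 0.372 (p = 0.267, adjusted 0.334) and 0.618 (p = 0.0469, adjusted 0.0695), and goblet cell genes 0.238 (p = 0.473, adjusted 0.473) and 0.264 (p = 0.436, adjusted 0.436). Within the 6 WT hosts r was 0.839 for the leukocyte score (permutation p adjusted over 5 relations 0.081), 0.965 for Ptprc (0.0486), 0.866 for smooth muscle (0.081), 0.194 for Y-linked genes (0.682) and 0.188 for goblet cell genes (0.682), and within the 5 male St2KO hosts 0.953 (0.0208), 0.962 (0.0208), 0.229 (0.783), 0.442 (0.763) and 0.175 (0.783) in the same order. Female donor marrow might be the source, but the sex of the donors was not given in the sources used here. Y-linked genes do not test this, because male libraries held 0.727% to 4.32% of the Xist level of the female library and a loss of that size would not show. Reads leaking from the female library would add a like amount to every library, but the highest male value was 5.94 times the lowest. Leakage alone would not give that range, but the range cannot exclude a like amount beneath another source. Y-linked genes in the female library were at 0.0842% of the male mean, which bears only on reads leaking into that library.

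Random regrouping of the same libraries addressed chance. For the average host effect the real grouping called 206 genes and the highest other 97. Only 1 of 100 splits, the real one, reached that count, so as many calls were rare under regrouping. The real grouping is counted among the 100, so the share could not be lower. Regrouping does not tell host genotype apart from cohort. For the average marrow effect and the interaction the real count was 0, which all 100 of 100 splits reach by construction, so they say nothing about chance there. The highest others were 12 and 386. Splits for the marrow effect were drawn within each host, whereas those for the interaction shuffled all 12 libraries. The latter can line up with the difference between hosts, so these values are not comparable, and the source of the 386 was not traced. The 10 splits of 3 against 3 are too few for a share under 0.05, and gave 4, 24 and 9 genes for the real groupings of the full, WT marrow host and St2KO marrow host comparisons with a highest other of 0 (1 of 10 each), and 0 with 0 (10 of 10) for both marrow comparisons.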
